A study of Homo sapiens with 28 samples.

How the data were processed

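Total RNA from 2 non-small cell lung cancer lines, A549 and H1299, was measured on 28 one-colour Affymetrix HG-U133 A 2.0 oligonucleotide arrays. Each line was exposed for 48 h to azacitidine or decitabine at 0.3, 1 or 3 µM, or to the vehicle dimethyl sulfoxide, with fresh drug every 24 h. The 14 groups of line, drug and dose held 2 arrays each. The labels name total RNA extraction with a column kit, amplification with biotin labelling, and MAS5 signal, without a version or a scaling target. Nothing in the labels says that replicates came from separate cultures, so every p measures the spread between these samples.

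The values deposited by the authors are MAS5 signal on a linear scale (intensity), 1 value for each of 22277 probe sets. The 2% trimmed mean of every array lay between 500.125 and 500.159, so the deposited arrays share 1 scaling target. The 25th percentile of the arrays ranged from 18.0 to 28.3 and the median from 92.7 to 123. The number of arrays limits the precision of every value here.

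The supplied probe table named 1 gene for 19070 probe sets, several genes for 1043 and none for 2164, of which 2108 were not control probe sets; 62 probe sets were controls. Looking up each Entrez identifier changed 0 symbols. The singly named probe sets stood for 11963 genes. A probe set was kept where its signal exceeded the array median on at least 2 arrays, which kept 13249, and each gene was represented by its kept probe set with the highest mean. This gave 8024 genes to test, of which 2600 had more than 1 kept probe set. Where another probe set of a called gene passed the threshold in the opposite direction, the gene is counted as disagreeing.

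Signals were taken as log2(signal + 32), so fold changes of dim genes are drawn toward 0. A limma model (limma 3.58.1 in R 4.3.3, tables read with data.table version 1.17.8) with 1 mean per group was fitted to all 28 arrays, leaving 14 residual degrees of freedom. Moderated statistics used eBayes with an intensity trend. Each of 27 comparisons was corrected by the Benjamini-Hochberg method at 0.05, two-sided. The comparisons were each dose against the vehicle of its line, azacitidine minus decitabine at each dose and over the 3 matched doses, 3 µM against 0.3 µM of each drug, and the differences between lines of the response at 3 µM and of the drug difference. Intervals cover 95%.

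The 21 gene lists were cancer-testis and germline genes, interferon-stimulated genes, antigen presentation, p53 targets, G1/S and replication, G2/M and mitosis, replication-dependent histones, cytidine analog uptake and metabolism, DNA methylation machinery, genes reported methylated in lung cancer, the integrated stress response, ribosome biogenesis, cytosolic ribosomal proteins, cholesterol synthesis, oxidative phosphorylation, NF-kB and inflammatory genes, NRF2 targets, epithelial markers, mesenchymal markers, leukocyte markers and housekeeping genes. They were written from general knowledge. Each was tested with camera, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data. A list mean is the mean log2 difference of its measured members. List means were also compared between the drugs by an exact permutation test within dose (216 relabelings, two-sided). The smallest p that this test can give is 0.00926. Values of p for lists are Benjamini-Hochberg adjusted over the 21 lists.

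The groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. For each of 6 main comparisons (each drug at 3 µM in each line, and the drug difference over doses in each line) the rule took the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap. It added the 4 largest called members of each list past camera, and 12 genes of the drugs' target, uptake and p53 pathways in every main comparison. For the differences between lines at 3 µM it took the 5 largest positive and the 5 largest negative genes. Of the 12 genes, 3 had no singly named probe set past the filter, and 1 gene that the rule took in H1299 is not reported here. Genes that the rule took and that lost their call in several alternatives are counted in the closing section and mostly left unnamed.

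Alternatives were quantile normalization, pseudocounts of 1 and 128, no filter, a filter at the 75th percentile, all kept probe sets, a fit of 1 line alone (7 residual degrees of freedom), eBayes without trend, a replicate block, a fold threshold of log2 1, the estimated correlation, and leaving out each array in turn. Median centring, the 25th percentile of the array as covariate, and leaving out 3 arrays in doubt were chosen after seeing the data. Scripts were tested on simulated data with 8024 genes, 100 of them changed at each size. In the comparisons of 3 µM with vehicle 45 to 59% of genes changed by log2 0.5 were found, and 90 to 95% of those changed by log2 1. The drug comparison over doses found 91 to 93% and 100%. False calls made up 3.54 to 4.61% of calls. Permutations and tables were made in R, and plots with matplotlib 3.10.9 in Python 3.11.15.

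Array quality was read from the 3'/5' signal ratios of the actin and GAPDH control probe sets. The labels call replicate 1 of A549 with decitabine 3 µM a repeat; it was kept. Control probe sets and probe sets with several genes or none were left out of the gene tests, since they name no single gene, and were tested apart.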

Results

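Gene expression was measured in A549 and H1299, lung cancer lines of which H1299 is known to lack p53, after 48 h with azacitidine or decitabine. Both drugs are cytidine analogs that trap DNA methyltransferases once they are in DNA. Azacitidine is a ribonucleoside and decitabine its 2'-deoxyribonucleoside. Each line had 2 arrays for the vehicle and 2 for each of 3 doses (0.3, 1 and 3 µM) of each drug, 28 arrays in 14 groups, and that number limits the precision. The question was how the responses to the drugs compare over a dose range. Values are log2 differences, signals are means ± SD, and for the genes with the largest changes from vehicle at 3 µM both treated arrays lay beyond both vehicle arrays.

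In A549, azacitidine at 3 µM raised stress-response genes that act downstream of the kinases phosphorylating eIF2. NIBAN1, a stress-induced regulator of translation, rose by 4.16 (SE 0.110, adjusted p = 1.03e-16), from a signal of 68.3 ± 10.5 to 1761 ± 42.3 (n = 2). TRIB3, a pseudokinase induced by ATF4, rose by 2.62 (SE 0.0842, adjusted p = 2.6e-15), from 1173 ± 19.7 to 7412 ± 577 (n = 2). The transcription factors ATF3 (2.75) and DDIT3 (2.10), the glycoprotein hormone gene STC2 (2.53), the hexokinase HK2 (2.91) and the growth inhibitor OSGIN1 (2.07) also rose. AGR2, a disulfide isomerase of secretory cells, fell by 3.51 (SE 0.120, adjusted p = 7.1e-15), from 2212 ± 395 to 164 ± 7.81 (n = 2). Other large falls were in fibrinogen FGB (-2.62), THSD7A (-2.56), the chemokine CCL2 (-2.47), glutathione peroxidase GPX2 (-2.38), TM4SF4 (-2.32), the junction protein JUP (-2.31) and the cytidine deaminase CDA (-2.25).

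Of the lists, the integrated stress response rose most in A549 with azacitidine at 3 µM, by a mean of 1.03 over 35 members (camera adjusted p = 6.7e-19, and adjusted p = 0.00077 with an estimated correlation); 29 members rose and none fell (31 adjusted over the list alone). Ribosome biogenesis genes rose by 0.46 (adjusted p = 2.8e-08), with DDX10 (1.50), GNL2 (0.97), NOP2 (0.90) and UTP14A (0.89) the largest, 22 of 38 (26 adjusted over the list alone). Cancer-testis genes, normally silent outside the germline, rose by 0.74 (adjusted p = 6.2e-05), led by MAGEA4 (2.16), MAGEA1 (1.88), MAGEB2 (1.84) and SPANXB1 (1.79), 12 of 19 (12 adjusted over the list alone). Cholesterol synthesis genes fell by a mean of 0.61 (list mean -0.605, adjusted p = 1.5e-07), with ACAT2 (-1.50), HMGCS1 (-1.14), MSMO1 (-1.12) and EBP (-1.07), 11 of 17 (12 adjusted over the list alone). Epithelial markers fell (-0.67, adjusted p = 2.7e-06; 10 of 17, and 10 adjusted over the list alone), among them JUP, ELF3 (-1.55), CDH1 (-1.46) and KRT19 (-1.21). Mesenchymal markers fell as well (-0.60, adjusted p = 3.0e-04; 9 of 20, and 9 adjusted over the list alone), with COL5A2 (-2.21), FN1 (-1.99) and S100A4 (-1.61).

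Cell cycle genes fell more mildly in A549 with azacitidine at 3 µM. The G2/M list fell by a mean of 0.26 (-0.265, adjusted p = 2.6e-08; 30 of 60 lower, 30 adjusted over the list alone), with CDCA3 (-0.91), SPC25 (-0.83), LMNB1 (-0.70) and PTTG1 (-0.69). The G1/S list fell (-0.15, adjusted p = 0.0032; 18 of 52 lower and 5 higher, 19 and 6 adjusted over the list alone), with CCND3 (-1.04), TK1 (-0.92) and RPA3 (-0.70). Genes reported methylated in lung cancer were lower (-0.30, adjusted p = 0.019; 11 of 25 lower and 6 higher, 12 and 6 adjusted over the list alone), through PTGS2 (-1.76), SPARC (-1.69), DKK3 (-1.66) and THBS1 (-1.48), while RASSF1 (1.43) and TSPYL5 (1.00) rose. With a pseudocount of 1 this call was lost (adjusted p = 0.0841). Oxidative phosphorylation (-0.14, adjusted p = 0.0012) and housekeeping genes (-0.12, adjusted p = 0.022) passed camera, but reached only adjusted p = 0.31 each with an estimated correlation. The housekeeping call was also lost without vehicle replicate 2 (adjusted p = 0.156) or azacitidine 3 µM replicate 1 (adjusted p = 0.0966). Of 44 oxidative phosphorylation genes 0 were higher and 14 lower (11 lower adjusted over the list alone). Of 23 housekeeping genes 1 was higher and 8 lower (1 and 8 adjusted over the list alone). In all, 3073 of 8024 genes changed, 1770 higher and 1303 lower, a split that turned to 1316 higher and 1680 lower after median centring of the arrays. Of 1104 called genes with several probe sets, 18 disagreed.

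Decitabine at 3 µM raised germline and p53-responsive genes in A549. LY6D, a surface protein of stratified epithelium, rose by 4.42 (SE 0.174, adjusted p = 3.4e-13), from 3.87 ± 2.82 to 732 ± 15.8 (n = 2). The sperm protein gene SPANXB1 rose by 3.99 and the germ cell RNA-binding protein DAZL by 3.76 (SE 0.162, adjusted p = 9.1e-13; 676 ± 95.03 against 20.5 ± 9.55, n = 2). MAGEA4 (3.28), MAGEB2 (2.82), the apoptosis inducer BIK (2.72), the chemokine CCL20 (2.57) and the germ cell gene TDRD12 (2.44) followed. The largest falls were smaller: the cell cycle repressor E2F8 (-1.25), the acetyltransferase subunit NAA15 (-1.24), CCDC88A (-1.22), the potassium channel KCNMA1 (-1.22) and the tubulin-binding protein STMN1 (-1.18).

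The p53 targets rose by a mean of 0.76 in A549 with decitabine at 3 µM (camera adjusted p = 1.2e-19, and 5.3e-07 with an estimated correlation); 33 of 40 members rose (33 adjusted over the list alone). PPM1D, a phosphatase that restrains p53, rose by 1.90, the death receptor FAS by 1.82, CYFIP2 by 1.58 and the cell cycle inhibitor CDKN1A by 1.61 (SE 0.0955, adjusted p = 1.3e-10), from 1168 ± 128.1 to 3613 ± 217 (n = 2). Cancer-testis genes rose by 1.31 (adjusted p = 2.1e-12), 14 of 19 (14 adjusted over the list alone). Interferon-stimulated genes were higher (0.26, adjusted p = 0.014; 10 of 30, 14 adjusted over the list alone), with IFITM3 (2.14), IFIH1 (1.11), IRF7 (0.90) and ISG15 (0.89). They did not pass with no filter on dim probe sets (adjusted p = 0.0530), with the stricter filter (adjusted p = 0.200) or without vehicle replicate 2 (adjusted p = 0.0569). Antigen presentation genes were higher (0.27, adjusted p = 0.019; 8 of 20, 8 adjusted over the list alone), with TAP1 (0.88), HLA-C (0.72) and HLA-B (0.63). Nor did they pass with no filter (adjusted p = 0.0795) or without vehicle replicate 2 (adjusted p = 0.0627). Epithelial markers passed camera (0.71, adjusted p = 3.8e-04; 8 of 17 higher, 8 adjusted over the list alone) with EPCAM (2.30), KRT19 (2.08), CDH1 (2.05) and CLDN7 (1.94), at adjusted p = 0.053 with an estimated correlation.

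Replication genes fell with decitabine at 3 µM in A549. The G1/S list fell (-0.36, adjusted p = 1.6e-11; 30 of 52 lower, 35 adjusted over the list alone), with MCM2 (-0.88) and the primase PRIM1 (-0.85). The G2/M list fell (-0.24, adjusted p = 5.5e-08; 26 of 60 lower, 27 adjusted over the list alone), with NCAPH (-0.96), MAD2L1 (-0.79) and ESPL1 (-0.76). Smaller list shifts passed camera only with the preset correlation. The integrated stress response was lower (-0.07, adjusted p = 0.036, and adjusted p = 0.30 with an estimated correlation). Of its members 5 rose, with ATF3 (1.45) and CTH (1.23), and 13 fell, with SLC7A11 (-0.92) and SLC3A2 (-0.70), or 5 and 14 adjusted over the list alone. NRF2 targets were lower (-0.13, adjusted p = 0.034, and adjusted p = 0.32 with an estimated correlation), 2 higher and 7 lower (2 and 7 adjusted over the list alone), and HMOX1 fell (-0.90). Cytidine analog metabolism was lower (-0.11, adjusted p = 0.041, and adjusted p = 0.16 with an estimated correlation), 4 higher and 7 lower (4 and 12 adjusted over the list alone). CAD, which starts pyrimidine synthesis, fell (-0.58). Each of these 3 calls was also lost without vehicle replicate 2 (adjusted p = 0.0977, 0.258 and 0.193) and without decitabine 3 µM replicate 2 (adjusted p = 0.0982, 0.201 and 0.112). In all 2067 genes changed, 1201 higher and 866 lower, and 1191 changed without replicate 1, the array labelled a repeat. Of 735 called genes with several probe sets, 10 disagreed.

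In H1299, azacitidine at 3 µM gave the largest response of the series. TAC1, the precursor of substance P, rose by 5.91 (SE 0.209, adjusted p = 3.6e-15), from 4.43 ± 4.496 to 2143 ± 19.8 (n = 2), and the uridine phosphorylase UPP1 rose by 4.62. DDIT3, which promotes death in prolonged stress, rose by 4.55 (SE 0.155, adjusted p = 2.1e-15), from 259 ± 17.3 to 6793 ± 208 (n = 2), and TRIB3 by 4.16. MAGEB2 (3.89), the lysosomal protein LAMP3 (3.65), the protease inhibitor CSTA (3.58) and the Notch effector HEY1 (3.18) also rose. The hormone gene STC1 fell by 3.54 (SE 0.113, adjusted p = 8.6e-16), from 1862 ± 2.83 to 131 ± 6.40 (n = 2). With it fell EMP1 (-2.99), the protease PLAU (-2.99), CPM (-2.82), and the lipid metabolism genes SCD (-2.93), INSIG1 (-2.51) and ACAT2 (-2.46).

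In H1299 with azacitidine at 3 µM the integrated stress response rose by a mean of 1.36 (camera adjusted p = 2.2e-14, and 8.4e-04 with an estimated correlation), 32 of 35 members (32 adjusted over the list alone), with ATF3 (3.14) and the amino acid transporter subunit SLC3A2 (2.44). The G2/M list fell by a mean of 1.13 (adjusted p = 6.5e-31, and 3.3e-06 with an estimated correlation), 59 of 60 members (59 adjusted over the list alone), with CDCA3 (-2.48), KIF20A (-2.08), LMNB1 (-2.04) and cyclin CCNB1 (-1.94), whose signal was 1444 against 5626 in vehicle. The G1/S list fell (-0.44, adjusted p = 9.5e-08; 33 of 52 lower and 4 higher, 33 and 4 adjusted over the list alone), with RPA3 (-1.42), LIG1 (-1.38), RRM2 (-1.24) and CDC45 (-1.24). Cholesterol synthesis fell by a mean of 0.94 (adjusted p = 3.5e-07; 13 of 17, 13 adjusted over the list alone), with EBP (-1.71) and LSS (-1.58) after ACAT2. Cancer-testis genes were higher (0.62, adjusted p = 0.049, and adjusted p = 0.28 with an estimated correlation). DAZL (1.64), MAGEC2 (1.56) and SSX1 (1.21) were among 10 of 19 that rose (10 adjusted over the list alone). The list call was also lost with a pseudocount of 1 (adjusted p = 0.155), with no filter, with the stricter filter, with a replicate block (adjusted p = 0.0552), and without vehicle replicate 1 (adjusted p = 0.0616) or azacitidine 3 µM replicate 2 (adjusted p = 0.0535).

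Other lists passed camera in H1299 with azacitidine at 3 µM only with the preset correlation. Oxidative phosphorylation was lower (-0.31, adjusted p = 9.4e-07, and adjusted p = 0.22 with an estimated correlation). Lower were 28 of 44 members (28 adjusted over the list alone), with ATP5MC1 (-1.10) and UQCRC2 (-0.79). Cytidine analog metabolism was lower (-0.09, adjusted p = 0.034, and adjusted p = 0.18 with an estimated correlation). NT5E (-1.25) and the thymidylate synthase TYMS (-1.21) were among 8 of 23 that fell (8 adjusted over the list alone), while 4 rose (4 adjusted over the list alone), among them UPP1, whose change was the largest of the list, and SLC29A3 (0.71). The call was lost without azacitidine replicate 1 (adjusted p = 0.0749). Cytosolic ribosomal proteins were lower (-0.12, adjusted p = 0.031, and adjusted p = 0.76 with an estimated correlation), but their mean turned to 0.01 under quantile normalization (adjusted p = 0.931). RPS9 (-0.43) and RPL10A (-0.35) were among 5 of 50 that fell (2 adjusted over the list alone). The list call was lost without vehicle replicate 2 (adjusted p = 0.275) or azacitidine replicate 1 (adjusted p = 0.0767). Housekeeping genes were lower (-0.16, adjusted p = 0.049, and adjusted p = 0.38 with an estimated correlation; 8 of 23 lower and 3 higher, 8 and 3 adjusted over the list alone). They did not pass under quantile normalization (adjusted p = 0.286) or without vehicle replicate 2 (adjusted p = 0.163) or azacitidine replicate 1 (adjusted p = 0.0767), nor with a replicate block (adjusted p = 0.0529). In all 4322 genes changed, 2587 higher and 1735 lower, against 1860 and 2511 after median centring, which moved the median of all genes from 0.08 to -0.10. Of 1534 called genes with several probe sets, 85 disagreed.

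Decitabine at 3 µM in H1299 raised DAZL by 5.63 (SE 0.162, adjusted p = 5.9e-16), from 3.53 ± 0.456 to 1722 ± 16.01 (n = 2), and MAGEB2 by 5.61. The antioxidant enzyme GPX1, with a signal of 7.80 ± 8.07 in vehicle, below the 25th percentile of every array, reached 789 ± 85.4 (4.38, n = 2). At such signals the size of the difference, as for DAZL, depends on the pseudocount. SSX1 (3.27), CCL20 (3.27), the muscle cytochrome oxidase subunit COX7A1 (3.06) and MAGEB1 (3.04) followed. The largest falls were in TBC1D22A (-2.19), the inositol phosphatase INPP5A (-1.95), VAC14 (-1.85), protein kinase PRKCA (-1.65), AGAP1 (-1.62), the AP-1 subunit FOSL1 (-1.57), INSIG1 (-1.51) and asparagine synthetase ASNS (-1.49).

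Inflammatory genes of the NF-kB list rose in H1299 with decitabine at 3 µM (0.71, camera adjusted p = 5.4e-07, and 0.0027 with an estimated correlation; 14 of 25, 15 adjusted over the list alone), with CXCL1 (1.61), LIF (1.56) and CXCL5 (1.53). Epithelial markers rose by 0.96 (adjusted p = 5.4e-07; 11 of 17, 12 adjusted over the list alone), with SPINT2 (2.74), EPCAM (2.51), KRT19 (2.35) and CLDN7 (2.31). Cancer-testis genes rose by a mean of 1.19 and a median of 0.09 (adjusted p = 6.7e-05; 7 of 19, 7 adjusted over the list alone). Genes reported methylated in lung cancer rose (0.57, adjusted p = 0.0015; 8 of 25 higher and 3 lower, 8 and 3 adjusted over the list alone), with SPARC (2.93), DKK1 (2.45), IGFBP3 (2.18) and WIF1 (2.12). Histone genes rose (0.37, adjusted p = 0.0034; 7 of 14, 8 adjusted over the list alone), with H2BC6 (0.91), H2BC12 (0.88) and H2BC21 (0.78). The p53 list rose (0.28, adjusted p = 2.4e-04; 17 of 40 higher and 3 lower, 18 and 6 adjusted over the list alone), with LIF, PLK2 (1.29), IER5 (1.10) and CDKN1A (1.00).

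Cholesterol synthesis fell with decitabine at 3 µM in H1299 (-0.47, adjusted p = 3.3e-05; 9 of 17, 9 adjusted over the list alone), with DHCR7 (-1.11), MSMO1 (-0.86) and HMGCS1 (-0.79). The G1/S list fell (-0.21, adjusted p = 7.3e-05; 21 of 52 lower and 3 higher, 24 and 3 adjusted over the list alone), with CDT1 (-0.95) and GINS1 (-0.73), while CCNE1 rose (0.72). The integrated stress response was lower (-0.27, adjusted p = 4.0e-04, and adjusted p = 0.061 with an estimated correlation). DDIT4 (-1.46) and PHGDH (-1.32) were among 18 of 35 that fell (20 adjusted over the list alone), and ATF3 (1.34) was among 6 that rose (7 adjusted over the list alone). Ribosome biogenesis was higher (0.23, adjusted p = 2.4e-04, and adjusted p = 0.061 with an estimated correlation), 18 of 38 members (20 adjusted over the list alone), with BYSL (0.85), PWP2 (0.60) and RRS1 (0.55). Mesenchymal markers were higher (0.45, adjusted p = 0.029; 7 of 20 higher and 3 lower, 8 and 3 adjusted over the list alone), with CCN2 (2.27), S100A4 (1.57) and ACTA2 (0.64). They lost their call with an estimated correlation (adjusted p = 0.13), with a pseudocount of 1 (adjusted p = 0.0564), in a fit of the line alone (adjusted p = 0.0686) and without decitabine replicate 1 (adjusted p = 0.0606). In all 2477 genes changed, 1305 higher and 1172 lower (1205 and 1265 after median centring), and of 811 called genes with several probe sets, 9 disagreed.

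**Figure D1:**
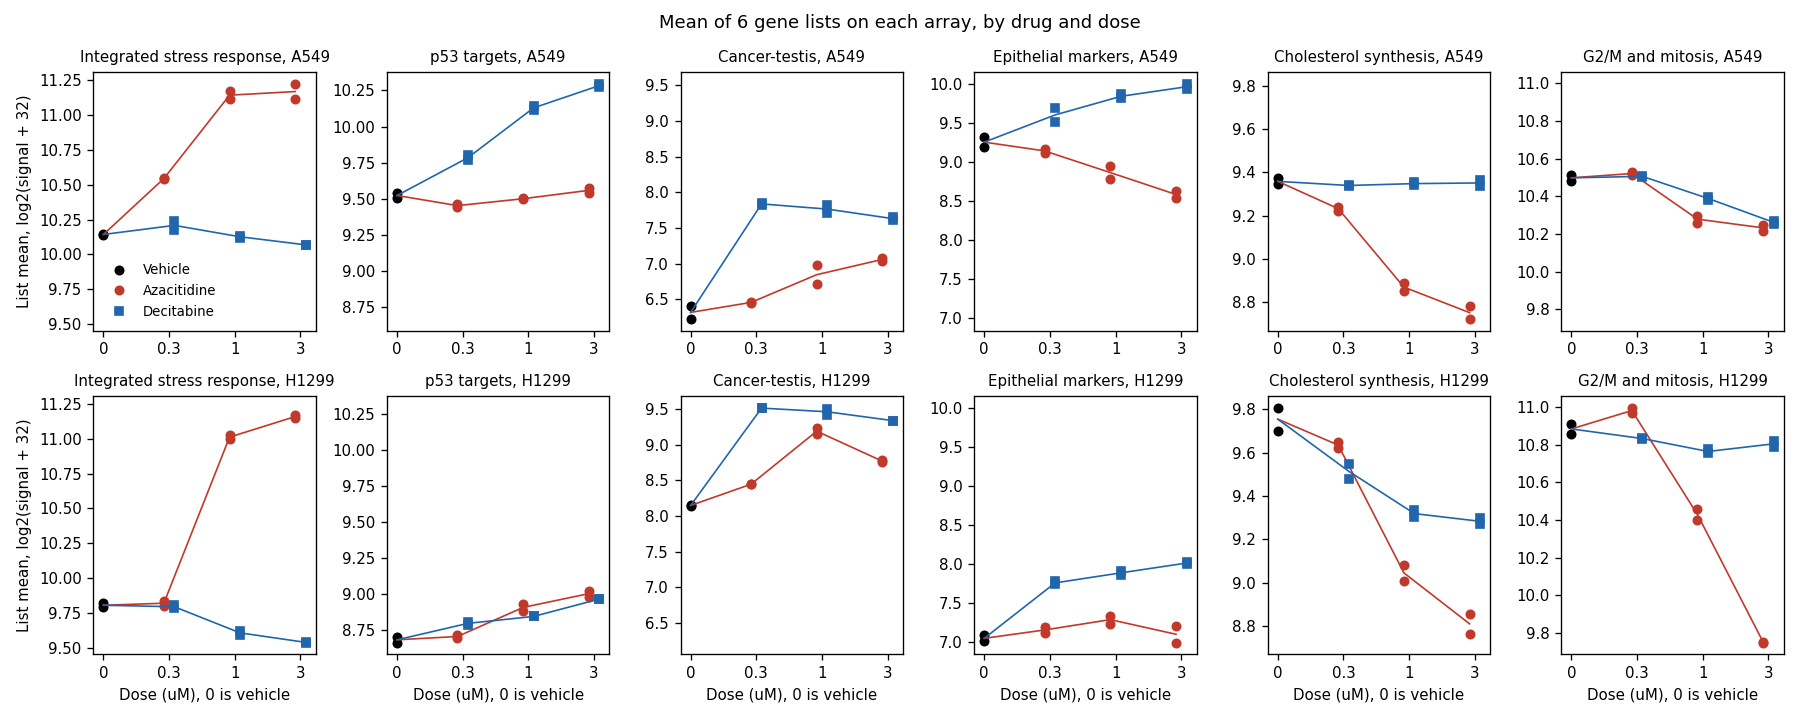
Mean log2(signal + 32) of 6 gene lists on each array (vertical axes) against dose in µM, with 0 for vehicle; each point is 1 array, red circles azacitidine, blue squares decitabine, black circles vehicle, and lines join group means. With azacitidine at 3 µM the integrated stress response list lies 1.03 above vehicle in A549 and 1.36 in H1299, while with decitabine the p53 list lies 0.76 above vehicle in A549.

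The response to dose differed by gene group. Cancer-testis genes were already at their highest mean with decitabine at 0.3 µM, 1.52 in A549 and 1.36 in H1299 (camera adjusted p = 1.7e-27 and 7.9e-13), where DAZL had risen by 3.87 and 5.36. With azacitidine at 0.3 µM DAZL did not pass the threshold in either line (-0.26 and 0.40). The integrated stress response rose with azacitidine at 0.3 µM in A549 (0.40, adjusted p = 2.1e-25; 17 of 35), with ASNS up by 1.16, and not in H1299 (0.01, adjusted p = 0.47). At 1 µM it had risen in both (1.00 and 1.21). The p53 list rose with each dose of decitabine in A549 (0.26, 0.61 and 0.76). The G2/M list in H1299 was at 0.10, -0.45 and -1.13 with rising azacitidine, and cholesterol synthesis at -0.12, -0.71 and -0.94. The value for cholesterol at 0.3 µM did not pass camera (adjusted p = 0.12) and that for G2/M did only with the preset correlation (adjusted p = 4.3e-04, and adjusted p = 0.11 with an estimated correlation).

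Counts of changed genes rose with dose for both drugs. With azacitidine at 0.3, 1 and 3 µM, 193, 2021 and 3073 genes changed in A549 and 452, 2828 and 4322 in H1299. With decitabine 616, 1325 and 2067 changed in A549 and 1416, 1870 and 2477 in H1299. At 0.3 µM azacitidine raised 93 genes and lowered 100 in A549 (122 and 72 after median centring). In H1299 it raised 194 and lowered 258 (259 and 180 after median centring, 231 and 203 after quantile normalization). Decitabine at 0.3 µM raised 344 and lowered 272 in A549 (426 of 642 higher after median centring). In A549 the 193 genes of azacitidine at 0.3 µM became 58 without vehicle replicate 1 and 51 and 61 without azacitidine replicates 1 and 2. The 2021 at 1 µM became 1307 without vehicle replicate 1 and 1292 without azacitidine replicate 2. The 616 genes of decitabine at 0.3 µM became 312 without vehicle replicate 1 and 294 and 329 without decitabine replicates 1 and 2. The 1325 at 1 µM became 830 without vehicle replicate 1 and 710 without decitabine replicate 2. In H1299 the 452 genes of azacitidine at 0.3 µM became 148 and 173 without vehicle replicates 1 and 2, and 170 and 210 without azacitidine replicates 1 and 2. The 1416 of decitabine at 0.3 µM became 813 and 911 without vehicle replicates 1 and 2, and 788 without decitabine replicate 1. The 1870 at 1 µM became 1179 without vehicle replicate 1 and 1224 without decitabine replicate 2.

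Expression at 3 µM was also compared with that at 0.3 µM. Between 0.3 and 3 µM of azacitidine 2760 genes differed in A549 (1687 higher at 3 µM and 1073 lower, or 988 and 1596 after median centring) and 4450 in H1299 (2704 and 1746, or 1712 and 2666). Between 0.3 and 3 µM of decitabine 722 differed in A549 (459 and 263, or 317 and 364) and 797 in H1299 (455 and 342, or 295 and 478). The 722 became 365 and 360 without decitabine 0.3 µM replicates 1 and 2, and 336 without decitabine 3 µM replicate 1. The 797 became 326 without decitabine 0.3 µM replicate 1, and 327 and 369 without decitabine 3 µM replicates 1 and 2. The median of all genes in the azacitidine dose comparison was 0.09 in A549 and 0.12 in H1299, and -0.03 and -0.10 after median centring.

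**Figure D2:**
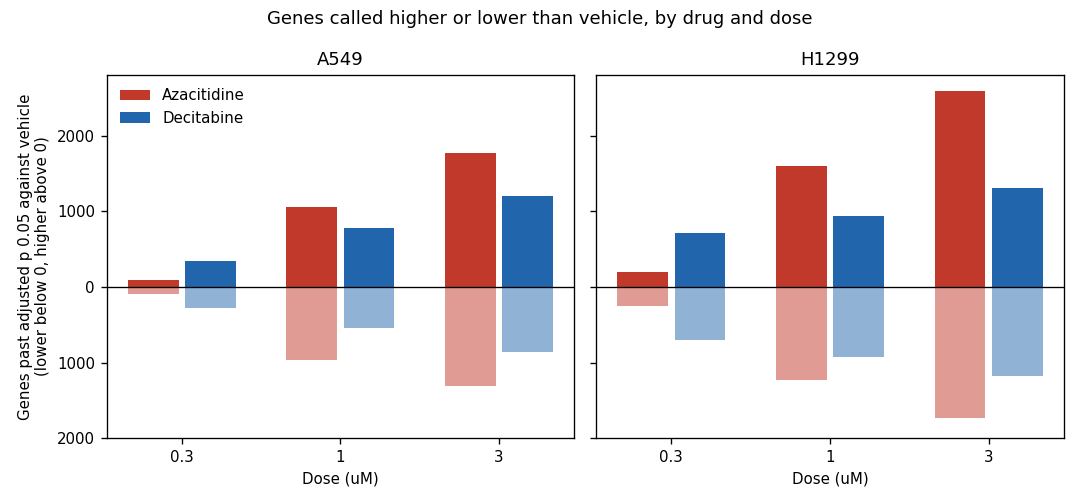
Number of genes past adjusted p 0.05 against vehicle (vertical axis, higher above 0 and lower below 0) at each dose in µM, red bars azacitidine and blue bars decitabine. Decitabine changed more genes at 0.3 µM (616 against 193 in A549, 1416 against 452 in H1299) and azacitidine more at 3 µM (3073 against 2067, 4322 against 2477).

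The drugs were compared directly at matched doses, 6 arrays against 6. In A549 stress-response genes were higher with azacitidine: NIBAN1 by 2.81 (SE 0.0636, adjusted p = 2.1e-18), TRIB3 by 2.01 and ASNS by 1.85 (5587 ± 1137 against 1507 ± 229, n = 6). They were followed by NUPR1 by 1.80, OSGIN1 by 1.47, CXCL2 by 1.42 and FAM216A by 1.37. Genes of germ cells and epithelia were lower with azacitidine: DAZL by -3.33 (SE 0.0936, adjusted p = 5.8e-17; 57.5 ± 56.0 against 741 ± 86.1, n = 6) and LY6D (-3.25). So were the water channel AQP3 (-3.18), CLIC3 (-2.60), SPARC (-2.46), E-cadherin CDH1 (-2.44), S100A2 (-2.38) and SERPINF1 (-2.33). CDKN1A was lower by -1.28 (SE 0.0551, adjusted p = 6.6e-14; 1160 ± 87.9 against 2926 ± 690, n = 6), with the p53 targets PPM1D (-1.37), DDB2 (-1.30) and FAS (-1.27).

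By exact permutation 16 of 21 list means differed between the drugs in A549, those given here at adjusted p = 0.013, which rests on the smallest p the test can give. The integrated stress response was higher with azacitidine by 0.82 (95% interval 0.769 to 0.869), 0.34, 1.02 and 1.10 at the rising doses, with 32 of 35 members higher (33 adjusted over the list alone). Ribosome biogenesis was higher by 0.33 (0.284 to 0.381; 29 of 38, 30 adjusted over the list alone), with DDX10 (1.00), UTP14A (0.76), RRP9 (0.69) and NOLC1 (0.66). G1/S genes were higher by 0.16 (0.141 to 0.177; 30 of 52 higher and 12 lower, 30 and 12 adjusted over the list alone), with CDT1 (0.96) and PRIM1 (0.86), while CCND3 was lower (-0.77). Cancer-testis genes were lower by -0.96 (-1.08 to -0.831; 14 of 19, 14 adjusted over the list alone). Epithelial markers were lower by -0.94 (-1.05 to -0.830; 12 of 17, 12 adjusted over the list alone), with EPCAM (-2.16) and MUC1 (-2.11), and p53 targets by -0.56 (-0.589 to -0.537; 31 of 40 lower and 4 higher, 32 and 4 adjusted over the list alone). Mesenchymal markers were lower by -0.55, with ACTA2 (-1.87) and COL6A3 (-1.40). Cholesterol synthesis was lower by -0.39, genes reported methylated by -0.36, leukocyte markers (4 measured) by -0.38, and NF-kB genes, antigen presentation and interferon-stimulated genes by -0.23 each. Histones (-0.21) and housekeeping genes (-0.11) were lower, and cytidine analog metabolism higher (0.06, adjusted p = 0.024, lost with a pseudocount of 1 at adjusted p = 0.338). The leukocyte call was lost with no filter, at -0.10 (adjusted p = 0.137).

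Camera called 12 of these lists in A549, and not leukocyte markers (adjusted p = 0.081), NF-kB genes (adjusted p = 0.069), housekeeping genes (adjusted p = 0.067) or cytidine analog metabolism (adjusted p = 0.28). Histones reached adjusted p = 0.047, and adjusted p = 0.059 with an estimated correlation or 0.0520 with a replicate block. The permutation test was not passed by DNA methylation machinery (-0.001, interval -0.027 to 0.025, adjusted p = 0.963), ribosomal proteins (0.06, -0.109 to 0.237, adjusted p = 0.408) or NRF2 targets (0.09, -0.003 to 0.188, adjusted p = 0.057). Nor was it by G2/M genes (-0.04, -0.065 to -0.018, adjusted p = 0.14) and oxidative phosphorylation (-0.07, -0.130 to -0.011, adjusted p = 0.194), although their intervals exclude 0. Ribosomal proteins and NRF2 targets passed after quantile normalization, and NRF2 targets without azacitidine 3 µM replicate 1 (adjusted p = 0.0458) or decitabine 3 µM replicate 1 (adjusted p = 0.0243). Camera called other lists in some alternatives. Leaving out azacitidine 1 µM replicate 1 or azacitidine 3 µM replicate 1 gave calls for NF-kB genes (adjusted p = 0.0398 and 0.0322) and ribosomal proteins (adjusted p = 0.0277 and 0.0322). Ribosomal proteins also passed without decitabine 1 µM replicate 2 (adjusted p = 0.0237) or decitabine 3 µM replicate 1 (adjusted p = 0.0124), the latter giving NRF2 targets too (adjusted p = 0.0473). Oxidative phosphorylation passed without azacitidine replicate 2 at 1 µM (adjusted p = 0.0485) or 3 µM (adjusted p = 0.0405), decitabine 1 µM replicate 1 (adjusted p = 0.0410) or decitabine 3 µM replicate 2 (adjusted p = 0.0392). The last 3 of these also gave housekeeping genes (adjusted p = 0.0414, 0.0410 and 0.0298). Both lists passed after quantile normalization (adjusted p = 0.0484 and 0.0397). Gene by gene 4365 differed over the doses, 2235 higher with azacitidine and 2130 lower (2018 and 2306 after median centring). At 0.3, 1 and 3 µM 455, 2753 and 4042 differed. The 455 became 180 and 190 without azacitidine replicates 1 and 2, and 167 and 188 without decitabine replicates 1 and 2. Of 1521 called genes with several probe sets, 53 disagreed.

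In H1299 azacitidine gave higher levels of CSTA (2.32), ASNS (2.20, SE 0.0403, adjusted p = 5.5e-20; 9935 ± 4097 against 2061 ± 788, n = 6), and NIBAN1 (2.01). The cystine transporter SLC7A11 (1.92), PYGB (1.68), MOCOS (1.52), INPP5A (1.48) and the serine synthesis gene PHGDH (1.47) were higher too. DAZL was lower by -4.15 (SE 0.0936, adjusted p = 7.9e-19; 79.4 ± 58.4 against 1705 ± 246, n = 6), with GPX1 (-3.57), the Wnt inhibitor DKK1 (-3.01), S100A6 (-2.80), CCL20 (-2.75), COX7A1 (-2.65) and SPINT2 (-2.54). CDKN1A did not pass between the drugs in H1299 (0.06, adjusted p = 0.348).

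By exact permutation 8 of 21 list means differed in H1299, at adjusted p = 0.028 unless given. The integrated stress response was higher with azacitidine by 1.02 (0.993 to 1.04, adjusted p = 0.049), at 0.03, 1.41 and 1.62 by dose. TRIB3 (2.25) and DDIT3 (1.84) were among 33 of 35 members higher (34 adjusted over the list alone). Its permutation call was lost without azacitidine 0.3 µM replicate 1 or decitabine 0.3 µM replicate 2 (adjusted p = 0.0729 in both). Lower with azacitidine were epithelial markers (-0.70, -0.802 to -0.605), with KRT19 (-2.32), CLDN7 (-1.97) and EPCAM (-1.90). Lower as well were cancer-testis genes (-0.64, -0.679 to -0.592), with SSX1 (-2.19) and MAGEB1 (-1.78), and mesenchymal markers (-0.54), with S100A4 (-1.92). So were NF-kB genes (-0.52), with CXCL5 (-1.55) and CXCL1 (-1.18), genes reported methylated (-0.43), with SPARC (-2.21) and IGFBP3 (-1.72), antigen presentation (-0.28), with TAP1 (-0.81), and ribosome biogenesis (-0.16), with RRS1 (-0.68). The number of members lower was 12 of 17, 9 of 19, 11 of 20, 12 of 25, 11 of 25, 11 of 20 and 20 of 38 in that order (12, 9, 11, 12, 11, 12 and 21 adjusted over the list alone), while 5 cancer-testis genes, 4 genes reported methylated and 4 of ribosome biogenesis were higher (5, 4 and 4 adjusted over the list alone).

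Camera called 13 lists in H1299, among them 5 that the permutation did not call. G2/M genes were lower with azacitidine over the doses (-0.41, interval -0.446 to -0.380, camera adjusted p = 9.7e-19, permutation adjusted p = 0.113), at 0.15, -0.33 and -1.05 by dose, 53 of 60 members (54 adjusted over the list alone). CDCA3 (-0.99), TOP2A (-0.83) and MKI67 (-0.79) were among them. G1/S genes (-0.09, camera adjusted p = 0.012), histones (-0.29, camera adjusted p = 0.0070) and cholesterol synthesis (-0.21, camera adjusted p = 0.020, and adjusted p = 0.056 with an estimated correlation) were lower over the doses too, though not at each dose. By rising dose they were at 0.11, -0.15 and -0.23, at -0.27, 0.04 and -0.62, and at 0.12, -0.27 and -0.47. Oxidative phosphorylation was lower by camera alone (-0.06, adjusted p = 0.048, and adjusted p = 0.55 with an estimated correlation), at 0.06, -0.01 and -0.24 by dose. The camera calls for cancer-testis genes (adjusted p = 0.022) and ribosome biogenesis (adjusted p = 5.7e-04) reached adjusted p = 0.17 and adjusted p = 0.063 with an estimated correlation. Neither test was passed by p53 targets (0.003, -0.026 to 0.032, adjusted p = 0.889), interferon-stimulated genes (0.01, -0.018 to 0.041, adjusted p = 0.70) or cytidine analog metabolism (0.01, -0.037 to 0.063, adjusted p = 0.594). Nor was either by ribosomal proteins (0.04, -0.073 to 0.145, adjusted p = 0.70), leukocyte markers (-0.10, -0.308 to 0.113, adjusted p = 0.246) and housekeeping genes (-0.05, -0.107 to 0.007, adjusted p = 0.332). DNA methylation machinery (0.10, 0.059 to 0.138, adjusted p = 0.181) and NRF2 targets (0.19, 0.124 to 0.266, adjusted p = 0.097) did not pass either, although their intervals exclude 0. The permutation called histones without decitabine 1 µM replicate 1 (adjusted p = 0.0432) and with no filter (adjusted p = 0.0243), and leukocyte markers without decitabine 3 µM replicate 1 (-0.14, adjusted p = 0.0432). Gene by gene 4322 differed over the doses, 2474 higher and 1848 lower, or 1879 and 2349 after median centring. At 0.3, 1 and 3 µM 511, 2718 and 4516 differed. The 511 became 323 and 281 without azacitidine replicates 1 and 2, and 254 without decitabine replicate 1. At 1 µM 1517 were higher and 1201 lower (1195 and 1476 after median centring). At 3 µM these were 2644 and 1872 (1912 and 2540 after median centring, which moved the median of all genes from 0.10 to -0.06). Of 1489 called genes with several probe sets, 85 disagreed.

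**Figure D3:**
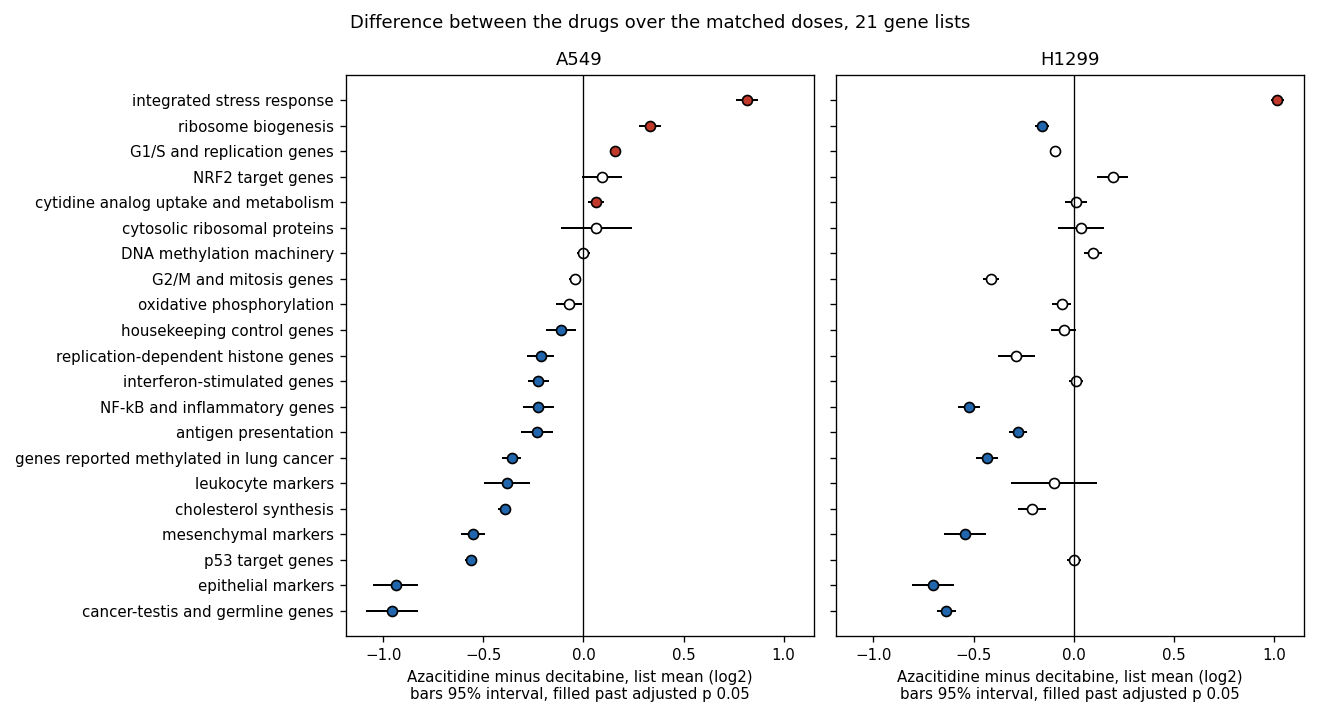
Azacitidine minus decitabine in the list mean over the 3 matched doses (log2, horizontal axis) for 21 gene lists in each line; points are differences, bars 95% intervals, and filled points passed the exact permutation test at adjusted p 0.05, red higher with azacitidine and blue lower. The integrated stress response lies at 0.82 in A549 and 1.02 in H1299, and the p53 list at -0.56 in A549 and 0.003 in H1299.

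Genes that process the drugs or are their targets responded unevenly. DNMT1, the maintenance methyltransferase, fell with decitabine at 3 µM in A549 (-0.34, adjusted p = 8.9e-04) and with azacitidine in H1299 (-0.82, adjusted p = 3.0e-09), and did not pass with azacitidine in A549 (-0.14, adjusted p = 0.127) or decitabine in H1299 (-0.18, adjusted p = 0.0574). The former passed after median centring (-0.22, adjusted p = 0.0215) and the latter with the stricter filter (adjusted p = 0.0433). Azacitidine minus decitabine was 0.18 for DNMT1 in A549 (adjusted p = 6.8e-04) and -0.30 in H1299 (adjusted p = 1.6e-06). DNMT3B was lower with azacitidine than with decitabine in both lines (-0.45, adjusted p = 3.2e-05, and -0.34, adjusted p = 6.3e-04). Against vehicle it was 0.12 with decitabine in A549 (adjusted p = 0.514) and 0.10 with azacitidine in H1299 (adjusted p = 0.561). It was 0.50 with decitabine in H1299 (adjusted p = 0.0052, but adjusted p = 0.0674 without decitabine replicate 1). It was -0.43 with azacitidine in A549 (adjusted p = 0.0109, but adjusted p = 0.18 without vehicle replicate 1 and adjusted p = 0.10 without azacitidine replicate 2). DNMT3A was higher with azacitidine than with decitabine in A549 (0.52, adjusted p = 2.5e-05), and in H1299 by 0.21 (adjusted p = 0.038), a call that median centring, quantile normalization and 9 of the arrays left out in turn ended. Against vehicle DNMT3A was 0.45 with azacitidine in A549 (adjusted p = 0.0174, but adjusted p = 0.203 without vehicle replicate 1, 0.0619 and 0.0722 without azacitidine replicates 1 and 2). It was -0.13 with decitabine in A549 (adjusted p = 0.541), 0.15 with azacitidine in H1299 (adjusted p = 0.403) and 0.03 with decitabine in H1299.

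The cytidine deaminase CDA fell with azacitidine at 3 µM in A549, from 135 ± 13.03 to 2.99 ± 0.749 (n = 2), and was higher with decitabine there (0.86, adjusted p = 0.0150). The decitabine call was lost without vehicle replicate 1 (adjusted p = 0.095) or decitabine replicate 2 (adjusted p = 0.114), and with a pseudocount of 1 (adjusted p = 0.497). Azacitidine minus decitabine was -1.56 (adjusted p = 1.2e-08). In H1299 CDA did not pass with azacitidine (-0.17, adjusted p = 0.61), decitabine (0.11, adjusted p = 0.779) or between the drugs (-0.24, adjusted p = 0.174), though the drug difference was -0.40 (adjusted p = 0.0134) without decitabine 1 µM replicate 2. Deoxycytidine kinase DCK did not pass with azacitidine in A549 (-0.10, adjusted p = 0.565) or H1299 (-0.08, adjusted p = 0.60), with decitabine in H1299 (-0.15, adjusted p = 0.398), or between the drugs (0.11, adjusted p = 0.184, and 0.13, adjusted p = 0.139). The drug difference in H1299 passed without decitabine 0.3 µM replicate 2 (0.18, adjusted p = 0.0362). With decitabine in A549 DCK was lower (-0.41, adjusted p = 0.0189), but not without decitabine replicate 1 (adjusted p = 0.246), vehicle replicate 1 (adjusted p = 0.0688) or vehicle replicate 2 (adjusted p = 0.0726). The ribonucleotide reductase subunit RRM2 fell with azacitidine in A549 (-0.52) and H1299 (-1.24) and with decitabine in A549 (-0.34), and not with decitabine in H1299 (-0.01, adjusted p = 0.921). Between the drugs it was lower with azacitidine (-0.19 and -0.43). RRM1 fell with azacitidine in H1299 (-0.53) and was lower with decitabine there (-0.39, adjusted p = 0.0022, but adjusted p = 0.0727 without vehicle replicate 1). It was lower with azacitidine in A549 (-0.27, adjusted p = 0.021, but adjusted p = 0.197 without azacitidine replicate 1 and adjusted p = 0.164 without vehicle replicate 2). It was -0.20 with decitabine in A549 (adjusted p = 0.102), and RRM1 did not pass between the drugs (0.04, adjusted p = 0.58, and -0.11, adjusted p = 0.0879). In H1299 that drug difference passed after median centring (-0.18, adjusted p = 0.0068) and without decitabine 1 µM replicate 2 (-0.14, adjusted p = 0.029).

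CDKN1A rose in H1299 with azacitidine (1.29) and decitabine (1.00) at 3 µM, and did not pass with azacitidine in A549 (-0.08, adjusted p = 0.523). MDM2, the ubiquitin ligase that p53 induces, was higher with decitabine in A549 (0.77, adjusted p = 0.0092), but adjusted p = 0.0572 without decitabine replicate 1 and 0.0856 without vehicle replicate 2. It did not pass with azacitidine in A549 (0.37, adjusted p = 0.17) or with azacitidine (0.02, adjusted p = 0.947) or decitabine (-0.20, adjusted p = 0.503) in H1299. Azacitidine minus decitabine was -0.50 for MDM2 in A549 (adjusted p = 0.0013) and 0.18 in H1299 (adjusted p = 0.22, but 0.30 and adjusted p = 0.033 without azacitidine 0.3 µM replicate 1).

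The lists that did not pass camera against vehicle at 3 µM are given here. In A549 with azacitidine they were interferon-stimulated genes (mean -0.01, median 0.01, adjusted p = 0.78), antigen presentation (mean -0.10, median 0.02, adjusted p = 0.28), p53 targets (mean 0.04, median -0.04, adjusted p = 0.78), and histones (-0.19, adjusted p = 0.087). There were also cytidine analog metabolism (-0.05, adjusted p = 0.52), DNA methylation machinery (mean 0.04, median -0.02, adjusted p = 0.61), ribosomal proteins (0.10, adjusted p = 0.38), NF-kB genes (-0.15, adjusted p = 0.26), NRF2 targets (mean -0.07, median 0.02, adjusted p = 0.60) and leukocyte markers (-0.02, adjusted p = 0.71). In A549 with decitabine they were histones (0.04, adjusted p = 0.68), DNA methylation machinery (0.02, adjusted p = 0.95), genes reported methylated (0.22, adjusted p = 0.17), ribosome biogenesis (-0.07, adjusted p = 0.23), and ribosomal proteins (0.08, adjusted p = 0.37). Further, they were cholesterol synthesis (-0.01, adjusted p = 0.64), oxidative phosphorylation (0.08, adjusted p = 0.26), NF-kB genes (0.12, adjusted p = 0.90), mesenchymal markers (0.20, adjusted p = 0.66), leukocyte markers (0.23, adjusted p = 0.34) and housekeeping genes (0.10, adjusted p = 0.34). In H1299 with azacitidine they were interferon-stimulated genes (mean -0.03, median 0.14, adjusted p = 0.77), antigen presentation (-0.20, adjusted p = 0.17), and p53 targets (0.32, adjusted p = 0.25; 18 of 40 higher and 9 lower, 19 and 9 adjusted over the list alone). The others were histones (-0.25, adjusted p = 0.23), DNA methylation machinery (0.22, adjusted p = 0.53), genes reported methylated (-0.04, adjusted p = 0.53), and ribosome biogenesis (mean 0.07, median -0.06, adjusted p = 0.90). Neither NF-kB genes (mean 0.12, median -0.02, adjusted p = 0.87), NRF2 targets (0.22, adjusted p = 0.58), epithelial markers (mean 0.05, median -0.07, adjusted p = 0.53), mesenchymal markers (-0.24, adjusted p = 0.16) nor leukocyte markers (0.59, adjusted p = 0.53) passed. In H1299 with decitabine they were interferon-stimulated genes (0.01, adjusted p = 0.88), antigen presentation (0.16, adjusted p = 0.079), G2/M genes (-0.08, adjusted p = 0.14), and cytidine analog metabolism (-0.10, adjusted p = 0.16). The rest were DNA methylation machinery (mean -0.05, median 0.01, adjusted p = 0.81), ribosomal proteins (0.03, adjusted p = 0.74), oxidative phosphorylation (-0.07, adjusted p = 0.14), NRF2 targets (-0.13, adjusted p = 0.11), leukocyte markers (0.52, adjusted p = 0.066) and housekeeping genes (mean 0.02, median -0.02, adjusted p = 0.88). Camera placed the p53 list and DNA methylation machinery lower in A549 with azacitidine, DNA methylation machinery lower in A549 with decitabine, and ribosome biogenesis and epithelial markers lower in H1299 with azacitidine, against the sign of their means.

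Some of these lists passed when 1 array was left out. In A549 with azacitidine ribosomal proteins were at 0.21 (adjusted p = 0.0050) without vehicle replicate 2 and 0.18 (adjusted p = 0.026) without azacitidine replicate 1, and histones at -0.23 (adjusted p = 0.0437) without vehicle replicate 1. In A549 with decitabine ribosomal proteins were at 0.19 (adjusted p = 0.0033) without vehicle replicate 2 and 0.20 (adjusted p = 0.0019) without decitabine replicate 2. Ribosome biogenesis passed there without vehicle replicate 1 (-0.09, adjusted p = 0.0351) or decitabine replicate 1 (-0.09, adjusted p = 0.0477), and oxidative phosphorylation without vehicle replicate 2 (0.12, adjusted p = 0.0415). In H1299 with decitabine leaving out vehicle replicate 1 gave calls for G2/M genes (-0.11, adjusted p = 0.0337), oxidative phosphorylation (-0.09, adjusted p = 0.0415), NRF2 targets (-0.19, adjusted p = 0.0238) and leukocyte markers (0.75, adjusted p = 0.0141). Leukocyte markers also passed there without decitabine replicate 1 (0.64, adjusted p = 0.0273) and after quantile normalization (adjusted p = 0.0456). Antigen presentation passed with the stricter filter (0.34, adjusted p = 0.0219) and in a fit of the line alone (adjusted p = 0.0497).

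Genes called with both drugs at 3 µM overlapped more in H1299. In A549 965 genes were called with both, 357 higher with both, 183 lower with both and 425 in opposite directions. Independent lists of these sizes would share 265, 141 and 386. In H1299 1601 were called with both, 693 higher, 483 lower and 425 opposite, against 421, 253 and 660 for independent lists. The 2 comparisons share the 2 vehicle arrays, and a fit that gives each drug a vehicle array of its own was not made. With no drug effect and shared vehicle, 100 simulations called at most 0.06 genes per drug on average, too few to judge overlap. Their fold changes correlated at 0.50. The observed correlation across genes, which are not independent replicates, was 0.0993 in A549 and 0.284 in H1299. The covariance was 0.0185 in A549 against a simulated 0.0134, and 0.0812 in H1299 against 0.0134, differences of 0.00507 and 0.0679.

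**Figure D4:**
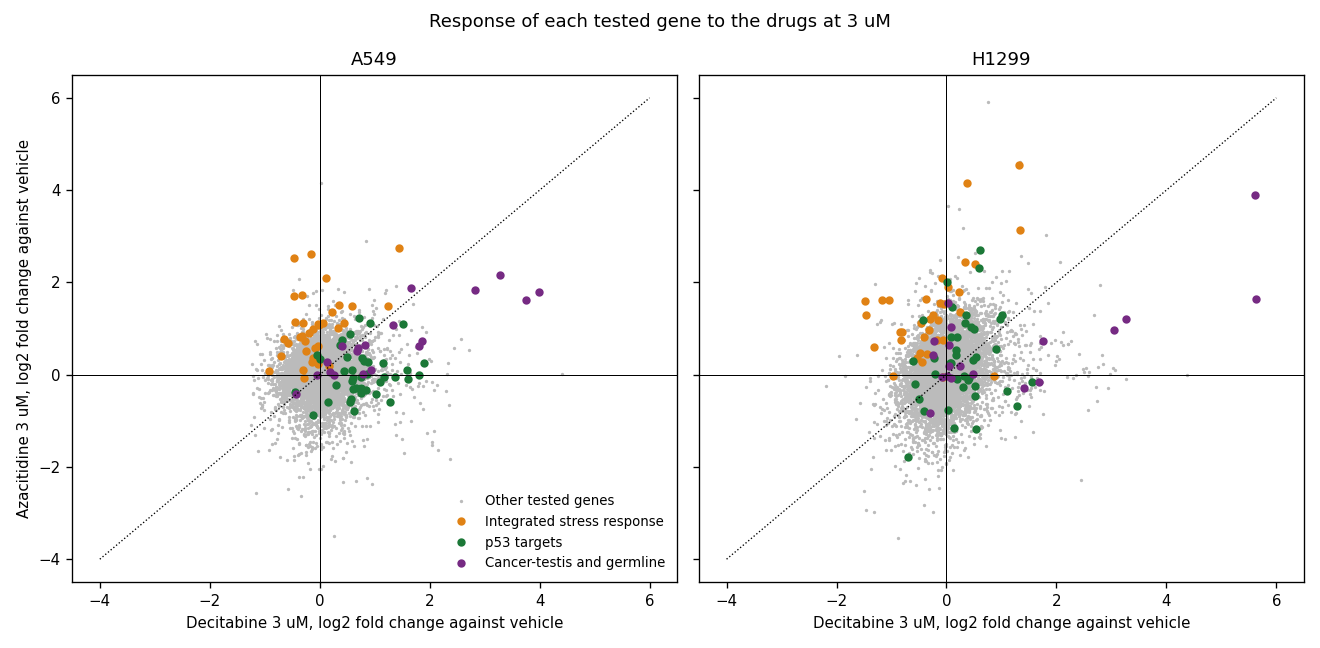
Log2 fold change of each tested gene against vehicle with azacitidine at 3 µM (vertical) and decitabine at 3 µM (horizontal); grey points are genes, colours mark integrated stress response, p53 and cancer-testis lists, and the dotted line marks equal change. Stress-response genes lie high on the vertical axis (mean 1.03 in A549, 1.36 in H1299) and some cancer-testis genes far along the horizontal (mean 1.31 and median 0.82 in A549, 1.19 and 0.09 in H1299, where 7 of 19 were called).

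Responses at 3 µM were compared between the lines as interactions, A549 minus H1299. For azacitidine the G2/M list was 0.87 higher in A549, since it fell further in H1299 (camera adjusted p = 7.4e-29; 55 of 60 members, 55 adjusted over the list alone). For azacitidine the integrated stress response did not pass (-0.33, adjusted p = 0.057), though it did under quantile normalization (adjusted p = 0.0107), with a pseudocount of 1 (adjusted p = 0.0434) and with no filter (adjusted p = 0.0166). It also passed without A549 vehicle replicate 1 (adjusted p = 0.0368), A549 azacitidine 3 µM replicate 2 (adjusted p = 0.0197), H1299 vehicle replicate 2 (adjusted p = 0.0412) or H1299 azacitidine 3 µM replicate 1 (adjusted p = 0.0353). For decitabine the p53 list was 0.48 higher in A549 (adjusted p = 4.1e-07; 21 of 40 members higher and 3 lower, 23 and 3 adjusted over the list alone), and the cancer-testis list did not pass (0.13, adjusted p = 0.78). Azacitidine and decitabine at 3 µM had 2511 and 1383 genes whose response differed between lines, and 3265 genes differed in the drug difference over doses; the closing section gives these with their genes and lists.

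RNA quality ratios moved with treatment alongside some gene groups. The actin 3'/5' ratio was 3.24 ± 0.223 in A549 vehicle and 3.46, 4.47 and 5.13 ± 0.322 at the rising doses of azacitidine, alongside the rise of the integrated stress response to 1.03. With decitabine it was 3.52, 4.25 and 3.79 (n = 2 each). In H1299 it was 5.32 ± 1.03 in vehicle, 5.29, 5.67 and 6.25 ± 0.0521 with azacitidine, and 3.99, 4.76 and 4.60 with decitabine. The GAPDH ratio was 1.00 in A549 vehicle and 1.08 with azacitidine at 3 µM, and 0.960 and 1.19 in H1299. The 25th percentile of signal was 28.3 on A549 vehicle replicate 1 and 20.1 on replicate 2.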

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

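The tests of array scaling, of the repeat array, of the vehicle arrays and of RNA from the other line were chosen after the result was seen, and the others before.

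Integrated stress response genes were higher with azacitidine at 3 µM, by 1.03 in A549 and 1.36 in H1299, while the actin and GAPDH 3'/5' ratios rose too. With both ratios in the model the means were 1.00 (0.936 to 1.07) and 1.26 (1.16 to 1.35). Genes called fell to 2693 and 3161. Their effect is read from replicate differences, so RNA quality loss with treatment stays open. Array scaling is argued against by means of 1.05 and 1.40 after quantile normalization. Azacitidine, as a ribonucleoside, may act through RNA as well as DNA, a hypothesis that expression cannot test. Amino acid supply, translation and eIF2 phosphorylation were not measured.

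The p53 targets were higher with decitabine at 3 µM in A549, where 1 of the 2 arrays is labelled a repeat. Array scaling is argued against by a mean of 0.78 after quantile normalization. The repeat array cannot be the whole source, since the list was also higher at 0.3 µM (0.26), on other arrays. Azacitidine minus decitabine (-0.56 at matched doses) cannot tell which drug moved. Low vehicle arrays may add to the rise, not its growth with dose (to 0.76). DNA damage activating p53 may underlie the rise, but decitabine also raised the list in H1299, which lacks p53 (0.28 at 3 µM). The p53 protein and DNA damage stay untested.

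Cancer-testis genes were higher with decitabine at 3 µM in both lines. RNA of the other line would bring all transcripts restricted to it. Genes bright (over 500) in the other line and dim (under 50) in vehicle gained a median of 0.237% of that signal in A549 (20 genes) and 0.267% in H1299 (116 genes), while the lower quartile of the share that the raised members needed was 6.71% and 1037%; a bright signal of 2000 had first left 3 genes in A549 and was lowered. Signal shared between gene copies is argued against as the whole source by 5 members outside the copy families (PRAME, DAZL, TKTL1, DDX43 and LUZP4), with means of 1.05 (0.845 to 1.25) and 1.93 (1.73 to 2.13) and 4 and 3 of the 5 called higher. DAZL carries much of these, and without it, a check chosen after the result was seen, the means were 0.37 (0.146 to 0.593) and 1.00 (0.780 to 1.23). Whether shared signal adds to the rise of the other members cannot be told. Loss of promoter methylation may be the source, but methylation was not analysed here.

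Differences between the lines were flagged where the interaction, A549 minus H1299, passed the test. For azacitidine at 3 µM 2511 genes differed, 1117 higher in A549 and 1394 lower (1436 and 1049 after median centring). The list means that differed were G2/M (0.87), ribosome biogenesis (0.39, 17 of 38 members higher, 18 adjusted over the list alone) and G1/S (0.29, 21 of 52 higher, 23 adjusted over the list alone). Others passed with the preset correlation only: cytosolic ribosomal proteins (0.21, and adjusted p = 0.66 with an estimated correlation), cholesterol synthesis (0.34, adjusted p = 0.076), oxidative phosphorylation (0.17, adjusted p = 0.49) and epithelial markers (-0.72, adjusted p = 0.076). Under quantile normalization ribosomal proteins fell to 0.04 (adjusted p = 0.570) and oxidative phosphorylation to 0.11 (adjusted p = 0.140), neither passing. The genes with the largest differences were HK2 (3.73), HBQ1 (2.98), FJX1 (2.93), CPM (2.82) and TM4SF1 (2.63), and TAC1 (-5.73), UPP1 (-3.51), AGR2 (-3.50), HEY1 (-3.25) and THSD7A (-3.17).

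For decitabine at 3 µM 1383 genes differed between the lines, 753 higher in A549 and 630 lower. The list means that differed were p53 targets (0.48), cholesterol synthesis (0.46), interferon-stimulated genes (0.25), NF-kB genes (-0.59), genes reported methylated (-0.35), histones (-0.33), ribosome biogenesis (-0.30), G2/M (-0.16) and G1/S (-0.15). Of these, interferon-stimulated genes did not pass with no filter (0.14, adjusted p = 0.0933), nor histones (adjusted p = 0.0521) and genes reported methylated (adjusted p = 0.0662) with the stricter filter. With an estimated correlation 3 more were lost: the integrated stress response (0.19, adjusted p = 0.26), oxidative phosphorylation (0.15, adjusted p = 0.49) and epithelial markers (-0.25, adjusted p = 0.18). The epithelial difference shrank to -0.03 with no filter (adjusted p = 0.273) and to -0.05 with the larger pseudocount (adjusted p = 0.595), which also ended the stress response call (0.14, adjusted p = 0.0735). Without the 3 arrays in doubt oxidative phosphorylation was at 0.07 (adjusted p = 0.549) and the stress response at 0.19 (adjusted p = 0.149). The genes with the largest differences were LY6D (4.42), SPANXB1 (3.95), MAGEA4 (3.35), TDRD12 (2.57) and VAC14 (2.39), and GPX1 (-3.79), MAGEB2 (-2.78), S100A6 (-2.78), GJA1 (-2.60) and KHDC1L (-2.55).

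The difference between azacitidine and decitabine itself differed between the lines for 3265 genes, 1404 higher in A549 and 1861 lower (1686 and 1528 after median centring). Of 100 relabelings of the drugs within dose 2, the real one included, gave as many, the highest other 3291. Relabeling drugs removes the drug effect itself, so it cannot test a difference between lines. The real one of 100 relabelings gave the most genes differing between the drugs: 4365 in A549 (next 3755) and 4322 in H1299 (next 3983). At best 1 in 100, the test leaves chance open. The lists were p53 targets (-0.57), ribosome biogenesis (0.49), G2/M (0.37) and G1/S (0.25), and with the preset correlation only NF-kB genes (0.29, and adjusted p = 0.14 with an estimated correlation) and interferon-stimulated genes (-0.24, adjusted p = 0.054). Both calls were also lost with the larger pseudocount. In this comparison the integrated stress response did not pass (-0.20, adjusted p = 0.057), though it did under quantile normalization (adjusted p = 0.0220), with a pseudocount of 1 (adjusted p = 0.0185), with no filter (adjusted p = 0.0192), with the stricter filter (adjusted p = 0.0430), with the 25th percentile as covariate (adjusted p = 0.0295) and without any 1 of 6 arrays. With an estimated correlation it was at adjusted p = 0.41. Cancer-testis genes passed with a pseudocount of 1 only (-0.58, adjusted p = 0.0185).

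Probe sets with no gene name or several, which the comparisons leave out, also changed against vehicle at 3 µM: of 1449 tested, 430 with azacitidine and 332 with decitabine in A549, and 648 and 352 in H1299.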

How the results depend on the processing

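The 25th-percentile covariate, median centring and the fit without 3 arrays in doubt were chosen after the data were seen; the other alternatives were planned. With 2 arrays per group each estimate rests on few values, an array left out leaves 1 in its group, which is then assumed to vary like the other groups, and dim genes are limited by the background that the pseudocount of 32 stands in for. Quantile normalization, both other pseudocounts, no filter, a fit of each line alone, eBayes without trend and median centring moved no total count by over 1.5 times. Median centring did move the numbers higher and lower within a total by more, as from 1687 and 1073 to 988 and 1596 for azacitidine between 3 and 0.3 µM in A549. Of 4321 values of named genes under alternatives other than left-out arrays, 4276 stayed called or uncalled as before, 41 lost the call and 4 gained it. Of 2259 such values of lists 2141 stayed as before, 78 lost the call, 37 gained it and 3 reversed, which is counted only where a call is involved. Among the values that stayed uncalled, 7 of genes and 64 of lists changed direction.

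The 3 reversals that involve a call were all of cytosolic ribosomal proteins. With azacitidine at 3 µM in H1299 the mean turned to 0.0108 (adjusted p = 0.931) under quantile normalization. Without the 3 arrays in doubt (replicate 1 of vehicle, azacitidine 3 µM and decitabine 3 µM in A549) it turned to -0.16 with decitabine at 3 µM in A549 (adjusted p = 8.4e-05) and to -0.19 in the interaction for decitabine (adjusted p = 4.2e-04), both uncalled in the main fit. Leaving out A549 vehicle replicate 2 or decitabine 3 µM replicate 2 called them in the opposite direction, at 0.19 and 0.20 in A549 (adjusted p = 0.0033 and 0.0019) and at 0.15 and 0.17 in the interaction (adjusted p = 0.0271 and 0.0166). The direction of this list thus depends on which arrays are kept. The cause was not tested.

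With the stricter filter, which tests fewer genes, 5 lists passed in H1299 with azacitidine at 3 µM instead of 9. With an estimated correlation the lists past camera were 6 instead of 10 in A549 with decitabine, 4 instead of 9 in H1299 with azacitidine, and 3 instead of 7 in the interaction for azacitidine. Counting all probe sets, which adds tests, gave in A549 3154 and 4640 for azacitidine at 1 and 3 µM and 3138 for decitabine at 3 µM, and in H1299 4344 and 6755 for azacitidine at 1 and 3 µM. For azacitidine minus decitabine it gave 6831 in A549 (4138 at 1 µM, 6248 at 3 µM) and 6713 in H1299 (4105 and 6985). It gave 6936 between 3 and 0.3 µM of azacitidine in H1299, 3823 in the interaction for azacitidine and 4963 in that of the drug difference.

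Asking for an absolute log2 fold change of at least 1 left, at 0.3, 1 and 3 µM, 12, 151 and 325 genes with azacitidine and 68, 117 and 186 with decitabine in A549. In H1299 it left 29, 247 and 839 with azacitidine and 158, 198 and 273 with decitabine. For azacitidine minus decitabine it left 189 in A549 (55, 282 and 579 by dose) and 194 in H1299 (77, 269 and 899). Between 3 and 0.3 µM it left 198 with azacitidine and 34 with decitabine in A549, and 803 and 29 in H1299. The interactions kept 594 (azacitidine), 321 (decitabine) and 247 (drug difference). The larger changes split otherwise than all calls did. For the drug difference 33 were higher with azacitidine and 156 lower in A549 (2235 and 2130 of all calls), and 72 and 122 in H1299 (2474 and 1848). By dose the majority turned at 3 µM in A549 (184 higher and 395 lower) and at 1 µM in H1299 (124 and 145). With azacitidine in A549 it turned at 1 µM (65 and 86), at 3 µM (130 and 195, against 1770 and 1303) and between 3 and 0.3 µM (85 and 113), and in H1299 at 0.3 µM (15 and 14). With decitabine at 3 µM 152 were higher and 34 lower in A549, and 200 and 73 in H1299. At adjusted p under 0.01 the calls shared in direction by the drugs at 3 µM were 249 instead of 540 in A549 and 722 instead of 1176 in H1299.

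With the 25th percentile of the array as covariate 67 genes changed with azacitidine at 0.3 µM in A549 instead of 193. Without the 3 arrays in doubt, which leaves fewer arrays, A549 had 61 and 1333 for azacitidine at 0.3 and 1 µM and 297, 830 and 972 for decitabine at 0.3, 1 and 3 µM. It had 366 between 3 and 0.3 µM of decitabine, 890 in the interaction for decitabine and 248 shared calls.

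Leaving out 1 array at a time, which leaves 1 array in a group, moved the counts in these ranges. In A549 they were 51 to 197 and 1292 to 1770 for azacitidine at 0.3 and 1 µM, and 294 to 585, 710 to 1086 and 1191 to 1795 for decitabine at 0.3, 1 and 3 µM. They were 167 to 190 for the drug difference at 0.3 µM and 336 to 505 for decitabine between 3 and 0.3 µM. In H1299 they were 148 to 210 for azacitidine at 0.3 µM, 788 to 1087 and 1179 to 1321 for decitabine at 0.3 and 1 µM, 254 to 404 for the drug difference at 0.3 µM and 326 to 593 for decitabine between 3 and 0.3 µM. Of 2676 values of named genes 60 lost their call when an array was left out and 4 gained one, and of 2184 values of lists 44 lost it and 46 gained one. Among the values that stayed uncalled, 10 of genes and 56 of lists changed direction.

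Of 21 pairs of groups, replicate differences correlated above 0.1 in 9 and below -0.1 in 4 in A549. In H1299, 3 lay above 0.1. Whether replicate numbers mark pairs is open. With a replicate block the counts against vehicle at 3 µM were 3161 for azacitidine and 2180 for decitabine in A549, and 4387 and 2560 in H1299. The block gave the drug difference of RRM1 in H1299 a call (-0.11, adjusted p = 0.0491) and ended 3 list calls by camera, those of cancer-testis genes (adjusted p = 0.0552) and housekeeping genes (adjusted p = 0.0529) with azacitidine at 3 µM in H1299 and of histones between the drugs in A549 (adjusted p = 0.0520).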

Other observations

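The share of raised genes below the array median was planned before its result was seen, and its repeat with no filter was chosen after.

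Genes of the germline that decitabine raised were close to their highest level at the lowest dose. MAGEB2 rose by 3.18 in A549 and by 5.60 in H1299 with decitabine at 0.3 µM, against 2.82 with azacitidine at that dose in H1299 and no call in A549 (0.30). SPANXB1 rose by 3.68 in A549 with decitabine at 0.3 µM and GPX1 by 4.94 in H1299. Of the epithelial markers EPCAM rose at that dose by 1.20 in A549 and 1.60 in H1299, and KRT19 by 2.20 in H1299. Their list passed camera in H1299 (8 of 17 higher, adjusted p = 3.1e-06), and in A549 only with the preset correlation (5 of 17 higher, adjusted p = 0.0027, and adjusted p = 0.168 with an estimated correlation). INPP5A, which encodes an inositol phosphatase, fell with decitabine at 0.3 µM in both lines (-0.58 in A549 and -1.52 in H1299).

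Dim genes made up a larger share of the genes raised by log2 1 or more at 3 µM with decitabine than with azacitidine. In A549 81 of 152 (53.3%) lay below their array's median in vehicle, against 37 of 130 (28.5%) raised by azacitidine. In H1299 it was 113 of 200 (56.5%) against 120 of 511 (23.5%). One-sided Fisher exact tests of decitabine against azacitidine gave adjusted p = 1.9e-05 and 2.5e-16, genes not being independent. The filter keeps a gene dim in vehicle only where other arrays exceed the median, so the test was repeated with no filter, which gave 117 of 188 against 51 of 144 in A549 and 138 of 224 against 143 of 534 in H1299 (adjusted p = 9.7e-07 and 5.6e-19). In H1299 the share is a matter of composition. Azacitidine raised slightly more dim genes there in both counts and more bright ones, so the test shows no excess of dim genes with decitabine. In A549 decitabine raised more dim genes in both counts. A signal below the median is not a silent gene, and demethylation was not measured.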
